A study of Mus musculus with 16 samples.

How the data were processed

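Mouse germline stem cells were cultured with GDNF and FGF2 on mouse embryonic fibroblasts, per the labels' protocols. Low oxygen was set by gassing plastic bags with 1% oxygen, and cells labelled Hif1a KO were treated with AxCANCre on the day of the hypoxia treatment. Total RNA (RNeasy Plus Micro Kit) went into TruSeq stranded mRNA libraries. There were 16 libraries in 8 groups of 2: DBA/2 wild type at 20% and 1% oxygen, Hif1a wild type at 20% and 1%, Hif1a KO at 20% and 1%, and Top1mt wild type and KO at 1%. The series text gives 2 days in 1% oxygen. Library names of the Hif1a groups at 1% carry "6d" and those of the Top1mt groups "2d", whose meaning is not given, and the DBA/2 names carry no time. Sample numbers in the names of the Hif1a libraries run on within each oxygen level and jump between them, and those at 1% carry an added "B", so these may be different sequencing sets. The DBA/2 numbers jump as well, from 13 and 14 at 20% to 17 and 18 at 1%. Numbers 17 and 18 occur in both lines. Whether wild type cells were given a control virus is not given in the sources used here.

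The authors deposited 1 table of CPM for 21924 protein-coding genes and 16 libraries. Trimming with cutadapt 1.16, alignment with STAR 2.6.0c, counting with HTSeq 0.11.2 and use of DESeq2 1.22.2 on build mm10 are named per the submitters' processing notes, without roles or settings. The annotation, the strand setting and the read filters were not stated. Each deposited column summed to 1000000, and 100% of values were whole multiples of the value of 1 read within a tolerance of 0.01. Reads per gene could therefore be recovered for all libraries. Of the 21924 symbols, 21888 matched the GENCODE M21 annotation of GRCm38 (mm10) once and 36 more than once, and coordinates come from that annotation.

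Depth ran from 11942104 to 25659895 reads on these genes, so that 1 read stood for 0.0390 to 0.0837 CPM. A value of 0 reads allows up to 3 reads by counting error, or 0.117 to 0.251 CPM, more if PCR copies were counted as reads. Replicates were compared gene by gene with a chi-square test on genes with at least 20 reads. Chi-square per gene ran from 1.79 in Hif1a wild type at 20% to 7.60 in Hif1a wild type at 1%, where 1 would mean counting error alone, and the replicates of no group were identical.

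The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1). All 16 libraries were fitted with 1 mean per group, empirical Bayes moderation with a trend, and no replicate block. Genes with a CPM of at least 1 in at least 2 libraries were kept (14841 genes). Calls were made at a Benjamini-Hochberg adjusted p of 0.05, with no limit on the fold. The plan named edgeR for whole counts. Since the file holds CPM, limma was used and edgeR was run as an alternative on the recovered reads. The comparisons were 1% against 20% oxygen in DBA/2 wild type, in Hif1a wild type and in the libraries labelled Hif1a KO. Further comparisons were KO against wild type in the Hif1a line at each oxygen level and in the Top1mt line at 1%. The last 2 were differences of oxygen responses: labelled Hif1a KO minus wild type (the interaction), and Hif1a wild type minus DBA/2. With 2 libraries a group, other splits of the libraries and outlier tests were not run.

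Gene lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment within a comparison and at least 3 tested members. The 24 lists were hypoxia targets outside glycolysis, glycolysis, HIF pathway components, stem cell self-renewal, spermatogonial differentiation, meiotic prophase, germ cell identity, feeder markers, testis somatic cell markers, leukocyte markers, pluripotency, nuclear oxidative phosphorylation, the mitochondrial genome, mitochondrial DNA maintenance, topoisomerases, antioxidant response, cell cycle, CDK inhibitors, p53 targets, stress and unfolded protein response, cholesterol synthesis, interferon response, immediate early genes and replication-dependent histones. Immediate early genes were listed as a sign of handling before lysis. Histones were listed as a sign of RNA quality and of RNA without a poly(A) tail. Mx2 of the interferon list was not in the table. Calls within a list are given from the adjustment over all genes and from one over the list alone. Where a camera call was lost with a correlation estimated from the data, that value stands beside it. Genes with log2 fold changes of at least 1 or at most -1 in DBA/2 cells formed 2 further lists, tested in the other lines.

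The genes named were chosen by a rule. It took the targeted gene in every library for each KO comparison. It took the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 5 in a compared group and no overlap between the libraries compared, the last not asked of the 2 differences of responses. It took up to 4 members with the smallest adjusted p of each list described, with a mean CPM of at least 1. It also took Hif1a, Epas1, Top1mt, Vegfa, Slc2a1, Bnip3, Pdk1, Gfra1, Kit, Cdkn1a and Mki67 where they help. Genes with only a Gm or Rik name were passed over. The test, the lists, the rule and all but 2 of the alternative settings were fixed before the data were examined.

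The alternative settings fixed in advance were pseudocounts of 0.25 and 4, no filter and a filter at CPM 5, median-of-ratios scaling, a replicate block within each line, a variance prior without a trend, and only the groups compared. Others were each library left out in turn, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, camera with an estimated correlation, fry, and the DBA/2 lists without a fold limit. Added after the data were examined were a rescaling of CPM to the geometric mean of the germ cell identity genes, called germ rescaling, which brings that list itself near 0 by construction, and a fit without 2661 feeder-associated genes. The latter are the feeder markers and genes at least 0.2 higher on the log2 scale in the libraries labelled Hif1a KO at 20% oxygen. The rule asked for no test and also takes genes raised by the label or the virus. That these genes come from feeder cells was not tested.

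The fits were tested on simulated data of the same size, with 50 changed genes at each fold of 1.5, 2, 3 and 4. For an oxygen comparison limma recovered 96% at 1.5-fold and 100% at 2-fold, with 11 false calls among 14641 unchanged genes. For the interaction it recovered 76% at 1.5-fold and 96% at 2-fold, with 20 false calls. camera called 0 of 200 unchanged lists of 20 genes in both. Genes were drawn independently in the simulation, and most were unchanged. It therefore cannot show how often camera makes false calls where genes correlate or where the mixture of cells shifts. Tables were read with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.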

Results

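RNA was measured in mouse germline stem (GS) cells, the cultured form of spermatogonial stem cells, which were grown with GDNF and FGF2 on a feeder layer of mouse embryonic fibroblasts. Sequencing of polyadenylated RNA gave 16 libraries in 8 groups of 2. DBA/2 wild type cells were kept at 20% or at 1% oxygen. Cells on a mixed 129 and C57BL/6 background, called the Hif1a line here, were kept at 20% or 1% oxygen, as wild type cells and as cells labelled Hif1a KO after treatment with AxCANCre, an adenovirus that carries Cre. C57BL/6 cells, wild type or labelled Top1mt KO and called the Top1mt line here, were kept at 1% oxygen only. Hif1a codes for the oxygen-labile subunit of hypoxia-inducible factor 1, and Top1mt for the topoisomerase that relaxes mitochondrial DNA. The deposited values were CPM (read counts scaled to a total of 1000000 per library) for 21924 protein-coding genes.

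Reads on these genes per library, recovered from the CPM steps, ranged from 11942104 to 25659895. The DBA/2 libraries held 21478642 and 23436895 reads at 20% oxygen and 20042031 and 22051828 at 1%. The Hif1a wild type libraries held 16324013 and 20918532 reads at 20% and 13721246 and 19766448 at 1%. The libraries labelled Hif1a KO held 11942104 and 18979146 reads at 20% and 15595077 and 25659895 at 1%. The Top1mt wild type libraries held 15959786 and 19305553 reads, and those labelled Top1mt KO 15720223 and 18163320. In what follows, a log2 fold change is of CPM + 1 and carries its standard error, a CPM value is the mean ± SD of 2 libraries, and adjusted p-values are from limma unless camera is named. A p-value here measures only the spread between these libraries.

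Both kinds of cell in the cultures left their mark on the values. The 24 feeder markers, fixed before the data were examined, summed to 9111 ± 1441 CPM in DBA/2 cells at 20% oxygen and 8505 ± 684 CPM at 1%. In the Hif1a wild type line the sum was 13775 ± 731 CPM at 20% and 36862 ± 6036 CPM at 1%. The libraries labelled Hif1a KO held 20974 ± 2449 CPM at 20% and 72626 ± 1197 CPM at 1%, or 7.26% of all reads counted. The Top1mt pair held 26931 ± 47.7 CPM in wild type and 51995 ± 853 CPM in KO libraries. The 16 germ cell identity genes summed to 6076 ± 154 and 6301 ± 41.4 CPM in DBA/2 cells at 20% and 1% oxygen, 4994 ± 39.0 and 5040.3 ± 255 CPM in Hif1a wild type cells, and 4232 ± 216 and 2269 ± 95.9 CPM in those labelled Hif1a KO. In the Top1mt pair this sum was 4323 ± 22.3 CPM in wild type and 3196 ± 56.4 CPM in KO libraries. Where these sums differ between groups, CPM do not separate a change in the mixture of cells from regulation within a cell.

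**Figure D1:**
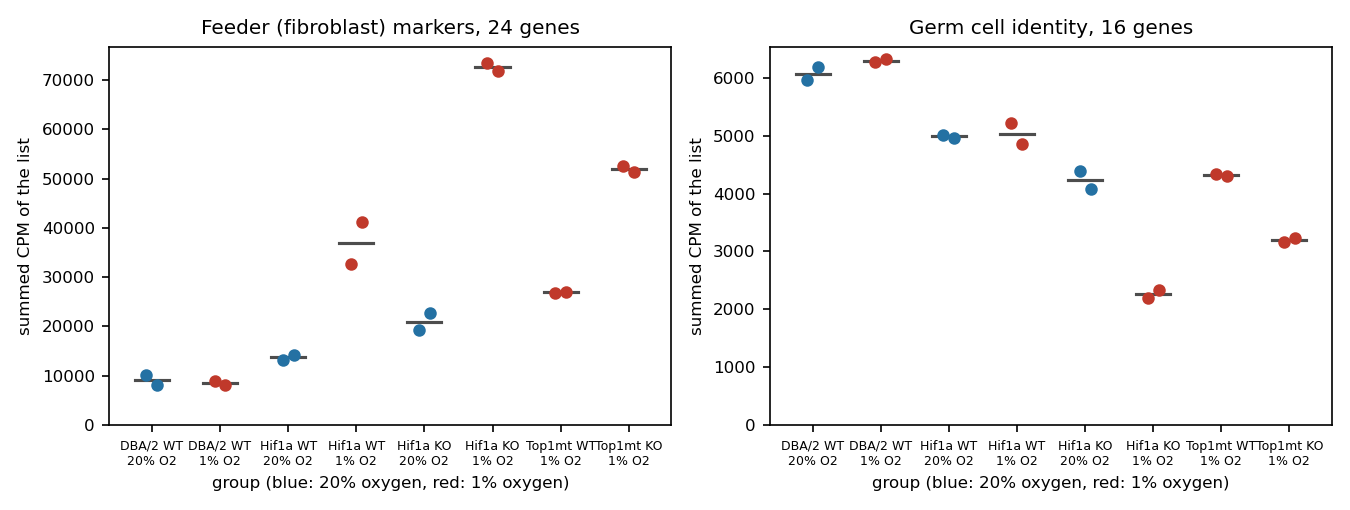
Summed CPM of the 24 feeder markers (left) and the 16 germ cell identity genes (right) in each library, with a line at each group mean (2 libraries per group, blue 20% and red 1% oxygen). The feeder sum ran from 8505 ± 684 CPM in DBA/2 cells at 1% oxygen to 72626 ± 1197 CPM in the libraries labelled Hif1a KO at 1%, which also had the lowest germ cell sum, 2269 ± 95.9 CPM.

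Wild type DBA/2 GS cells at 1% oxygen were compared with the same cells at 20%. The cells raised genes for glucose uptake, glycolysis and lactate export together with the long-known hypoxia targets, while the Hif1a transcript itself did not change by the test. Genes that hold spermatogonia in the self-renewing state fell, while meiotic prophase genes rose. Sterol synthesis genes fell and immediate early genes rose. Of these list calls only that of the hypoxia targets held with an estimated correlation. Of 14841 genes tested, 4725 rose and 3789 fell, 356 and 349 of them at least 2-fold, and the median over all genes was 0.04. Sample numbers in the DBA/2 library names jump between oxygen levels (13 and 14 at 20%, 17 and 18 at 1%). A difference between sequencing sets can therefore not be excluded for this comparison.

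Hypoxia targets outside glycolysis rose almost as a block in DBA/2 cells: 33 of 35 rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 fold change of 0.93 (camera adjusted p = 6.4e-20, and 0.031 with an estimated correlation). Ero1l, an oxidase for protein folding in the endoplasmic reticulum, rose from 81.8 ± 2.23 to 499 ± 29.2 CPM (log2 fold change 2.59 ± 0.05, adjusted p = 3.0e-19). Adm, which codes for the vessel-dilating peptide adrenomedullin, rose from 3.19 ± 0.354 to 40.5 ± 1.19 CPM. Bnip3, a trigger of mitophagy, rose by 2.49 ± 0.06 and the collagen lysyl hydroxylase Plod2 by 1.51 ± 0.04. The angiogenic factor Vegfa rose from 59.8 ± 10.6 to 114 ± 2.79 CPM. The oxygen sensors Egln3 (1.85 ± 0.06) and Egln1 (1.45 ± 0.06), which hydroxylate HIF for degradation, rose as well. Hif1a stayed at 109 ± 11.8 and 108 ± 6.25 CPM (adjusted p = 0.92), and its paralogue Epas1 did not change by the test (adjusted p = 0.59). Over the HIF pathway components 5 of 11 rose and 1 fell (5 and 1 adjusted over the list alone). Their median was 0.04 (camera adjusted p = 0.18).

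Glycolysis genes moved further: 20 of 22 rose and 1 fell (20 and 1 adjusted over the list alone). Their median was 1.51 (camera adjusted p = 1.2e-16, adjusted p = 0.097 with an estimated correlation). The gene with the largest rise was Slc16a3 (chromosome 11, 120948480 to 120960868, mm10), the lactate exporter, which went from 4.24 ± 0.388 to 116 ± 6.42 CPM (log2 fold change 4.47 ± 0.08, adjusted p = 8.0e-19). The phosphofructokinases Pfkp and Pfkl rose by 2.92 ± 0.05 and 3.03 ± 0.09, triosephosphate isomerase Tpi1 by 2.41 ± 0.07 and the glucose transporter Slc2a1 by 1.87 ± 0.05. Pdk1, which keeps pyruvate out of mitochondria, was the exception and fell slightly from 152 ± 8.49 CPM (-0.15 ± 0.05, adjusted p = 0.013), a call that ended without either of 2 libraries (20% replicate 2 or 1% replicate 2). Among the 10 largest rises were also the hypoxia targets Stc2 (3.11 ± 0.13), a glycoprotein hormone, and Ankrd37 (3.20 ± 0.11). Outside the lists these were the inducible nitric oxide synthase Nos2 (3.59 ± 0.14), the epithelial keratin Krt19 (3.68 ± 0.14) and the secreted mucin Muc2 (4.05 ± 0.15).

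Self-renewal genes fell in DBA/2 cells: 3 of 30 rose and 23 fell (3 and 23 adjusted over the list alone). Their median was -0.50 (camera adjusted p = 3.7e-09, adjusted p = 0.097 with an estimated correlation). The transcription factor Zbtb16 (PLZF) fell from 492 ± 8.64 to 171 ± 9.36 CPM (log2 fold change -1.52 ± 0.05, adjusted p = 5.5e-15). Both parts of the GDNF receptor fell, Gfra1 (-1.19 ± 0.07) and Ret (-0.93 ± 0.04), and so did the GDNF-induced repressor Bcl6b (-1.26 ± 0.07). Among meiotic prophase genes 15 of 19 rose and 1 fell (16 and 1 adjusted over the list alone). Their median was 0.40 (camera adjusted p = 8.3e-04, adjusted p = 0.43 with an estimated correlation). Meioc, which holds cells in extended prophase, rose by 1.45 ± 0.08 and the meiotic cohesin Rec8 by 1.31 ± 0.08. The meiosis gatekeeper Stra8, a member of the differentiation list, rose by 0.88 ± 0.08, from 86.9 to 161 CPM. Spo11, which cuts DNA in prophase, fell (-1.44 ± 0.12). Over the differentiation list 7 of 16 rose and 3 fell (7 and 3 adjusted over the list alone). Their median was 0.09 (camera adjusted p = 0.26), with the transcription factor Dmrtb1 rising by 1.31 ± 0.11 and the RNA-binding factor Nanos3 falling (-0.93 ± 0.09).

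Cholesterol synthesis genes fell in DBA/2 cells: 0 of 24 rose and 18 fell (0 and 19 adjusted over the list alone). Their median was -0.38 (camera adjusted p = 1.9e-07, adjusted p = 0.15 with an estimated correlation). Lanosterol synthase Lss fell (-0.85 ± 0.05), as did the mevalonate decarboxylase Mvd (-0.93 ± 0.09). The immediate early genes were listed as a sign of handling before lysis, which was not tested apart from oxygen level or label in any comparison. Of these, 12 of 12 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 1.11 (camera adjusted p = 7.2e-09, adjusted p = 0.28 with an estimated correlation), led by Fos, from 58.8 ± 0.783 to 275 ± 37.5 CPM. Of the genes of the mitochondrial genome 7 of 7 rose and 0 fell (7 and 0 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 0.018, adjusted p = 0.53 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of 0.06 (camera adjusted p = 0.7), with the hypoxia-induced subunits Ndufa4l2 (2.85 ± 0.13) and Cox4i2 (2.18 ± 0.17) far above it. The CDK inhibitor Cdkn1c rose by 1.29 ± 0.08 and the cyclin Ccne1 by 1.05 ± 0.09. Of the feeder markers 6 of 24 rose and 10 fell (6 and 10 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.18): the matrix proteoglycan Lum fell (-2.56 ± 0.10) and Ccn2 rose by 1.74 ± 0.11. Germ cell identity genes had a median of 0.00 (camera adjusted p = 0.83). Outside the lists, the ganglioside synthase St8sia1 had the largest fall (-3.02 ± 0.15), followed among the genes named here by the matrix protein Mgp (-2.64 ± 0.15).

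The Hif1a wild type line put the same question to cells of another background. Its hypoxia targets and glycolysis genes rose as well, and the Hif1a transcript rose too. Most feeder markers rose, most self-renewal genes fell, and the sterol synthesis genes called were higher with 1 exception. Of these list calls only that of the hypoxia targets held with an estimated correlation. Of 14841 genes, 2737 rose and 5140 fell, 459 and 231 of them at least 2-fold, and the median over all genes was -0.09. Rescaling by median-of-ratios factors raised the share of risen genes among those called from 34.7% to 49.8%. The library names at 1% oxygen carry a mark of 6 days, where the series text gives 2 days, and the time in low oxygen is therefore uncertain for this line. As in DBA/2 cells, the sample numbers in the library names of the Hif1a line part the libraries at 20% oxygen from those at 1%. A difference between sequencing sets therefore cannot be told apart from oxygen level.

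Of the hypoxia targets outside glycolysis 32 of 35 rose and 0 fell (32 and 0 adjusted over the list alone) in Hif1a wild type cells. Their median was 0.81 (camera adjusted p = 3.4e-28, and 0.01 with an estimated correlation). The carbonic anhydrase Car9, which exports acid, rose from 0.375 ± 0.0105 to 17.3 ± 3.82 CPM (log2 fold change 3.72 ± 0.16, adjusted p = 2.1e-13). Vegfa rose by 2.47 ± 0.09, Bnip3 by 2.58 ± 0.06, Adm by 3.37 ± 0.09 and Egln3 by 2.08 ± 0.06. Hif1a rose from 117 ± 1.11 to 251 ± 0.0154 CPM (log2 fold change 1.09 ± 0.06, adjusted p = 9.0e-12). Of the HIF pathway components 5 of 11 rose and 4 fell (6 and 4 adjusted over the list alone). Their median was 0.14 (camera adjusted p = 0.0505). Of the glycolysis genes 18 of 22 rose and 2 fell (18 and 2 adjusted over the list alone). Their median was 0.93 (camera adjusted p = 5.9e-17, adjusted p = 0.11 with an estimated correlation). Slc16a3 rose by 3.67 ± 0.08, the enolase Eno2 by 2.69 ± 0.08, phosphoglycerate kinase Pgk1 by 2.29 ± 0.09 and Slc2a1 by 1.30 ± 0.05. Pdk1, which fell in DBA/2 cells, rose here from 54.4 ± 1.93 to 122 ± 4.44 CPM (log2 fold change 1.15 ± 0.05, adjusted p = 3.2e-13). The largest rises were those of Nos2, from 0.583 ± 0.392 to 55.3 ± 8.27 CPM (5.17 ± 0.14), and of Ndufa4l2 (5.04 ± 0.13), which tempers the first respiratory complex in hypoxia.

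Feeder markers rose in this line: 18 of 24 rose and 2 fell (18 and 3 adjusted over the list alone). Their median was 1.05 (camera adjusted p = 3.7e-13, adjusted p = 0.21 with an estimated correlation). Collagen Col3a1 rose from 1045 ± 92.2 to 6284 ± 1059 CPM, Dcn by 2.05 ± 0.10, Postn by 1.86 ± 0.08 and Lum by 2.14 ± 0.10. The cyclin Ccnd1, of the cell cycle list, fell (-1.39 ± 0.10). Among the 10 largest rises were the secreted proteins Rarres2, a chemoattractant (4.86 ± 0.10), the pentraxin Ptx3 (3.60 ± 0.11) and the serum amyloid Saa3 (3.45 ± 0.12). Germ cell identity genes had a median of -0.10 (camera adjusted p = 0.76) and were level in sum. Self-renewal genes fell: 1 of 30 rose and 23 fell (2 and 23 adjusted over the list alone). Their median was -0.48 (camera adjusted p = 4.6e-07, adjusted p = 0.18 with an estimated correlation). Ret fell (-0.82 ± 0.04), Gfra1 (-0.81 ± 0.07), Ccnd2 (-0.78 ± 0.05) and Plvap, a marker of a subset of GFRA1-positive spermatogonia (-2.36 ± 0.12), from 17.2 ± 0.191 to 2.56 ± 0.529 CPM. Of the differentiation genes 0 of 16 rose and 8 fell (0 and 8 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.071), Kit falling (-0.48 ± 0.06). Of the meiotic prophase genes 9 of 19 rose and 3 fell (9 and 3 adjusted over the list alone). Their median was 0.20 (camera adjusted p = 0.0075, adjusted p = 0.41 with an estimated correlation), among them Meioc (0.78 ± 0.08) and the cohesin Stag3 (0.53 ± 0.05).

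Of the cholesterol synthesis genes 12 of 24 rose and 1 fell (12 and 1 adjusted over the list alone) in Hif1a wild type cells. Their median was 0.24 (camera adjusted p = 1.1e-05, adjusted p = 0.19 with an estimated correlation). The demethylase Cyp51 rose by 0.62 ± 0.05, squalene epoxidase Sqle by 0.47 ± 0.05 and the sterol oxidase Msmo1 by 0.74 ± 0.08. Immediate early genes rose with a median of 1.11 (camera adjusted p = 3.0e-12, adjusted p = 0.18 with an estimated correlation), Fos by 1.92 ± 0.08 and Fosb by 2.37 ± 0.11. Of the p53 targets 9 of 18 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0075, adjusted p = 0.29 with an estimated correlation), and Cdkn1a (p21) rose by 1.30 ± 0.10. Stress and unfolded protein response genes had a median of 0.08 (camera adjusted p = 0.029, adjusted p = 0.21 with an estimated correlation), with Atf3 rising by 2.26 ± 0.09, and the histones a median of 0.47 (camera adjusted p = 0.029, adjusted p = 0.22 with an estimated correlation). The quinone reductase Nqo1, an NRF2 target, fell (-1.69 ± 0.13), within an antioxidant list whose median was 0.02 and mean -0.13 (camera adjusted p = 0.79). Mki67, a marker of dividing cells, did not change by the test (adjusted p = 0.6). Top1mt fell from 53.9 ± 1.87 to 34.4 ± 0.752 CPM (-0.63 ± 0.07), and also in DBA/2 cells (-0.37 ± 0.07).

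Whether the lines differ was tested as the Hif1a wild type response minus the DBA/2 response. Hypoxia targets outside glycolysis were not called as a list, and their members went both ways, while most glycolysis genes rose further in DBA/2 cells. Sterol synthesis and feeder markers were set apart in the opposite direction. None of these list calls held with an estimated correlation. The difference was called for 6830 genes, 2248 positive and 4582 negative, with a median over all genes of -0.13; after median-of-ratios scaling this median was -0.015 and the positive share went from 32.9% to 51.0%. Of the hypoxia targets 9 of 35 were higher and 14 lower (9 and 16 adjusted over the list alone). They had a median difference of -0.12 and a mean of -0.02 (camera adjusted p = 0.89); the median was 0.00 after that scaling. For glycolysis the median was -0.55 (camera adjusted p = 1.3e-04, adjusted p = 0.52 with an estimated correlation), with Pfkp at -1.87 ± 0.07, the neuronal-type glucose transporter Slc2a3 at -1.62 ± 0.09 and Pdk1 opposed at 1.30 ± 0.07. Vegfa rose further in Hif1a wild type cells (1.54 ± 0.13), as did Hif1a (1.10 ± 0.08). Cholesterol synthesis had a median of 0.56 (camera adjusted p = 1.3e-15, adjusted p = 0.073 with an estimated correlation), with Cyp51 at 0.91 ± 0.07 and Hmgcs1 at 0.83 ± 0.07. Feeder markers had a median of 1.21 (camera adjusted p = 2.9e-13, adjusted p = 0.52 with an estimated correlation), with Lum at 4.70 ± 0.14. Outside the lists the acute-phase inhibitor Serpina3n stood at 4.67 ± 0.13, while the rise of Krt19 was smaller than in DBA/2 cells (-3.21 ± 0.19). Line, time in low oxygen and library set were confounded in this difference.

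The 2 lines share no library. Calls in the same direction numbered 1402 up and 2244 down, against 871 and 1312 for independent lists. In opposite directions 1246 genes were called, for which no number for independent lists was computed. Across the 14841 genes the responses correlated with r = 0.32, where genes are not independent replicates. The 356 genes that rose at least 2-fold in DBA/2 cells had a median of 0.39 in Hif1a wild type cells, where 196 rose and 38 fell (camera adjusted p = 2.2e-22, and 0.018 with an estimated correlation). The 349 that fell had a median of -0.45, where 60 rose and 206 fell (camera adjusted p = 4.3e-05, adjusted p = 0.13 with an estimated correlation). In the libraries labelled Hif1a KO the same lists had medians of 0.47 (camera adjusted p = 2.6e-15, and 0.030 with an estimated correlation) and -0.53 (camera adjusted p = 0.74, and -0.659 to -0.320 over left-out libraries), beside -0.29 over all genes.

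**Figure D2:**
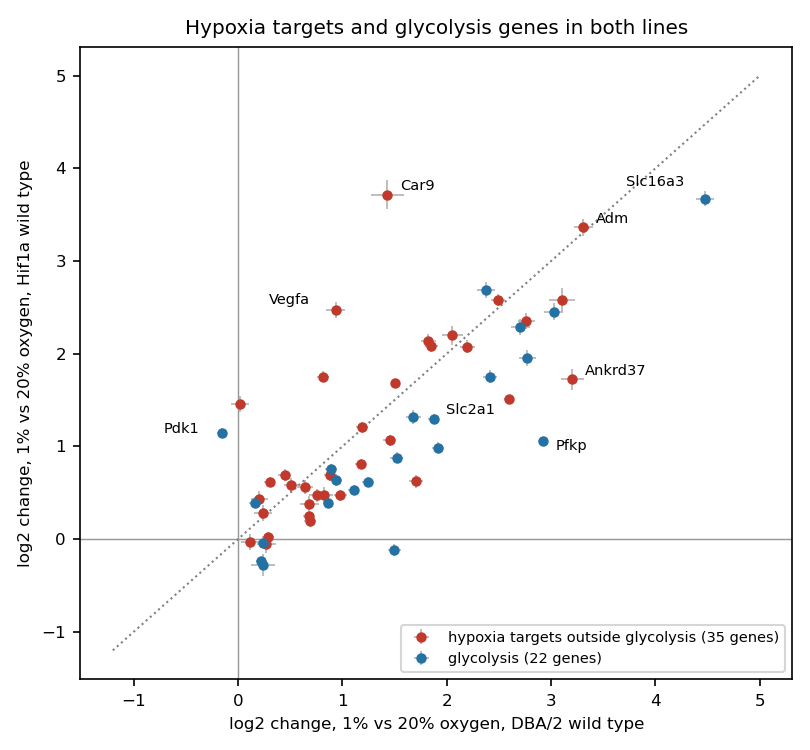
Log2 fold change of CPM + 1 from 20% to 1% oxygen in DBA/2 (horizontal) and Hif1a wild type cells (vertical) for 35 hypoxia targets (red) and 22 glycolysis genes (blue), with standard errors and a dotted line of equal change. Slc16a3 lay at 4.47 and 3.67, while Vegfa (0.93 and 2.47) and Pfkl (3.03 and 2.45) lay on either side of that line.

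The libraries labelled Hif1a KO were made to ask how far the response to low oxygen needs HIF1A, and the targeted transcript was not lower in them. Hif1a (chromosome 12, 73901375 to 73947530, mm10) stood at 139 and 142 CPM in the libraries labelled Hif1a KO at 20% oxygen and at 618 and 593 CPM at 1%. The Hif1a wild type libraries stood at 117 and 118 CPM at 20% and at 251 in both libraries at 1%. Gene-level values cannot show a deleted exon, and the labels do not name the deleted part, so a transcript without it would be counted here. Directions from these libraries therefore rest on the label alone. Whether the wild type cells were given a control virus is not stated in the sources used here, so the label also carries the virus treatment.

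**Figure D3:**
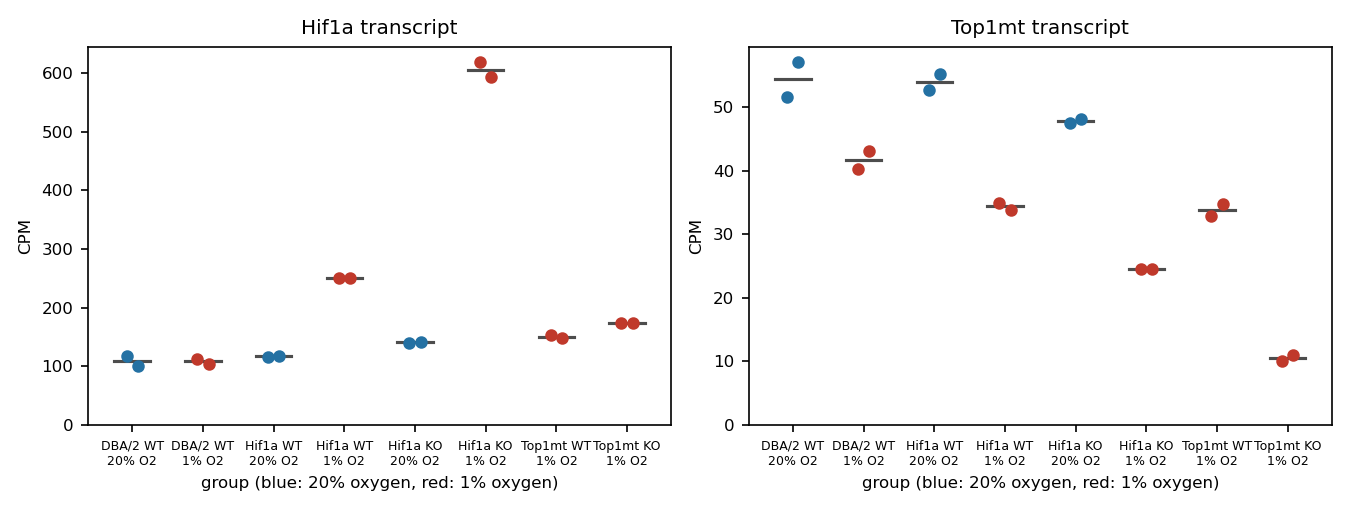
CPM of Hif1a (left) and Top1mt (right) in each library, with a line at each group mean (2 libraries per group, blue 20% and red 1% oxygen). Hif1a was highest in the libraries labelled Hif1a KO at 1% oxygen (618 and 593 CPM), and Top1mt lowest in those labelled Top1mt KO (9.99 and 10.96 CPM).

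At 1% oxygen the libraries labelled Hif1a KO raised hypoxia targets, glycolysis genes and the p53 target Cdkn1a. Self-renewal genes fell, and the meiotic and cell cycle lists as a whole fell relative to all reads but not relative to germ cell identity genes. All feeder markers rose. Of these list calls only that of the hypoxia targets held with an estimated correlation. Of the genes tested, 3747 rose and 8118 fell, 1232 and 1405 of them at least 2-fold. The median over all genes was -0.29, and median-of-ratios scaling moved log2 fold changes by 0.35. Values below are best read against that median, since this scaling raised the share of risen genes among calls from 31.6% to 53.2%. Rescaling to the germ cell identity genes, chosen after the data were examined, moved them by 0.93 and made 90.1% of calls rises.

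Of the hypoxia targets outside glycolysis 29 of 35 rose and 3 fell (29 and 3 adjusted over the list alone) in the libraries labelled Hif1a KO. Their median was 1.37 (camera adjusted p = 5.3e-17, and 0.0499 with an estimated correlation). Bnip3 rose to 176 ± 3.36 CPM (log2 fold change 3.55 ± 0.06, adjusted p = 4.8e-19). Car9 rose by 4.80 ± 0.16, Egln3 by 3.25 ± 0.06, Vegfa by 2.73 ± 0.09, the stress gene Ndrg1 by 2.53 ± 0.05 and Plod2 by 2.25 ± 0.04. Glycolysis had a median of 1.47 (camera adjusted p = 1.7e-12, adjusted p = 0.1 with an estimated correlation). Of these, 18 of 22 rose and 2 fell (18 and 2 adjusted over the list alone), with Slc16a3 rising by 4.91 ± 0.08, Eno2 by 3.66 ± 0.08, Pfkl by 3.17 ± 0.09 and Pdk1 by 1.49 ± 0.05. Of the HIF pathway components 6 of 11 rose and 3 fell (6 and 4 adjusted over the list alone). Their median was 0.20 (camera adjusted p = 0.0474, adjusted p = 0.1 with an estimated correlation). The largest rise was that of Ndufa4l2 (6.06 ± 0.13), and the fatty acid carriers Fabp4 (4.68 ± 0.16) and Fabp5 (4.18 ± 0.11), the metalloreductase Steap4 (4.81 ± 0.13) and Nos2 (4.91 ± 0.14) were among the 10 largest.

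Of the feeder markers 24 of 24 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 1.47 (camera adjusted p = 4.5e-15, adjusted p = 0.1 with an estimated correlation), Col3a1 from 1306 ± 253 to 10144 ± 56.2 CPM. Of the germ cell identity genes 0 of 16 rose and 16 fell (0 and 16 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 1.6e-05, adjusted p = 0.17 with an estimated correlation), the piRNA-pathway Argonaute Piwil2 from 516 ± 30.6 to 243 ± 4.14 CPM. Self-renewal genes had a median of -1.14 (camera adjusted p = 1.3e-06, adjusted p = 0.1 with an estimated correlation). Of these, 0 of 30 rose and 28 fell (0 and 28 adjusted over the list alone), Ret falling (-1.44 ± 0.04), Gfra1 (-1.42 ± 0.07) and the RNA-binding factor Lin28a (-1.28 ± 0.05); the list median was -0.28 after germ rescaling. The differentiation list had a median of -0.98 (camera adjusted p = 0.0079, adjusted p = 0.1 with an estimated correlation), and -0.17 after germ rescaling, with 2 called higher and 5 lower. From deposited CPM 1 of 16 rose and 13 fell (1 and 13 adjusted over the list alone), with Kit at -1.67 ± 0.06 and Sohlh2 at -1.17 ± 0.07. The meiotic list had a median of -0.77 (camera adjusted p = 0.0069, adjusted p = 0.38 with an estimated correlation), which turned to 0.11 after germ rescaling. Of these, 0 of 19 rose and 17 fell (0 and 17 adjusted over the list alone). Cell cycle genes had a median of -0.92 (camera adjusted p = 5.9e-06, adjusted p = 0.1 with an estimated correlation), and 0.01 after germ rescaling. Of these, 1 of 26 rose and 25 fell (1 and 25 adjusted over the list alone), with the replication helicase subunits Mcm5 (-1.37 ± 0.04) and Mcm3 (-1.19 ± 0.04) and with Mki67 (-1.01 ± 0.06).

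Of the p53 targets 14 of 18 rose and 1 fell (14 and 1 adjusted over the list alone) in the libraries labelled Hif1a KO. Their median was 0.77 (camera adjusted p = 5.7e-07, adjusted p = 0.1 with an estimated correlation). Cdkn1a rose from 195 ± 22.0 to 767 ± 18.3 CPM, the kinase Plk2 by 1.87 ± 0.07 and cyclin G1 (Ccng1) by 1.30 ± 0.06. The CDK inhibitors had a median of 0.53 (camera adjusted p = 0.0029, adjusted p = 0.1 with an estimated correlation). Of these, 6 of 7 rose and 0 fell (6 and 0 adjusted over the list alone). Stress and unfolded protein response genes had a median of 0.56 (camera adjusted p = 0.0015, adjusted p = 0.1 with an estimated correlation). Of these, 13 of 20 rose and 6 fell (13 and 6 adjusted over the list alone), with Atf3 at 2.87 ± 0.09 and the ER chaperone Hspa5 at 0.86 ± 0.05. Immediate early genes had a median of 1.64 (camera adjusted p = 3.3e-09, adjusted p = 0.1 with an estimated correlation), histones 1.15 (camera adjusted p = 0.0056, adjusted p = 0.1 with an estimated correlation) and leukocyte markers 0.78 (camera adjusted p = 0.014, adjusted p = 0.1 with an estimated correlation). Genes that maintain and transcribe mitochondrial DNA had a median of -0.59 (camera adjusted p = 0.017, adjusted p = 0.1 with an estimated correlation), which was 0.25 after germ rescaling. Of these, 0 of 17 rose and 16 fell (0 and 16 adjusted over the list alone); the polymerase Polg fell (-0.78 ± 0.05) and the packaging factor Tfam (-0.82 ± 0.06). Nuclear oxidative phosphorylation genes had a median of -0.21 and a mean of -0.03 (camera adjusted p = 0.28), which turned to a median of 0.15 after median-of-ratios scaling and 0.73 after germ rescaling. Of the cholesterol synthesis genes 10 of 24 rose and 10 fell (10 and 10 adjusted over the list alone) from deposited CPM. Their median was 0.03 (camera adjusted p = 0.19), or 0.38 with 16 rising and 2 falling after median-of-ratios scaling, and 0.94 with 24 rising after germ rescaling.

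**Figure D4:**
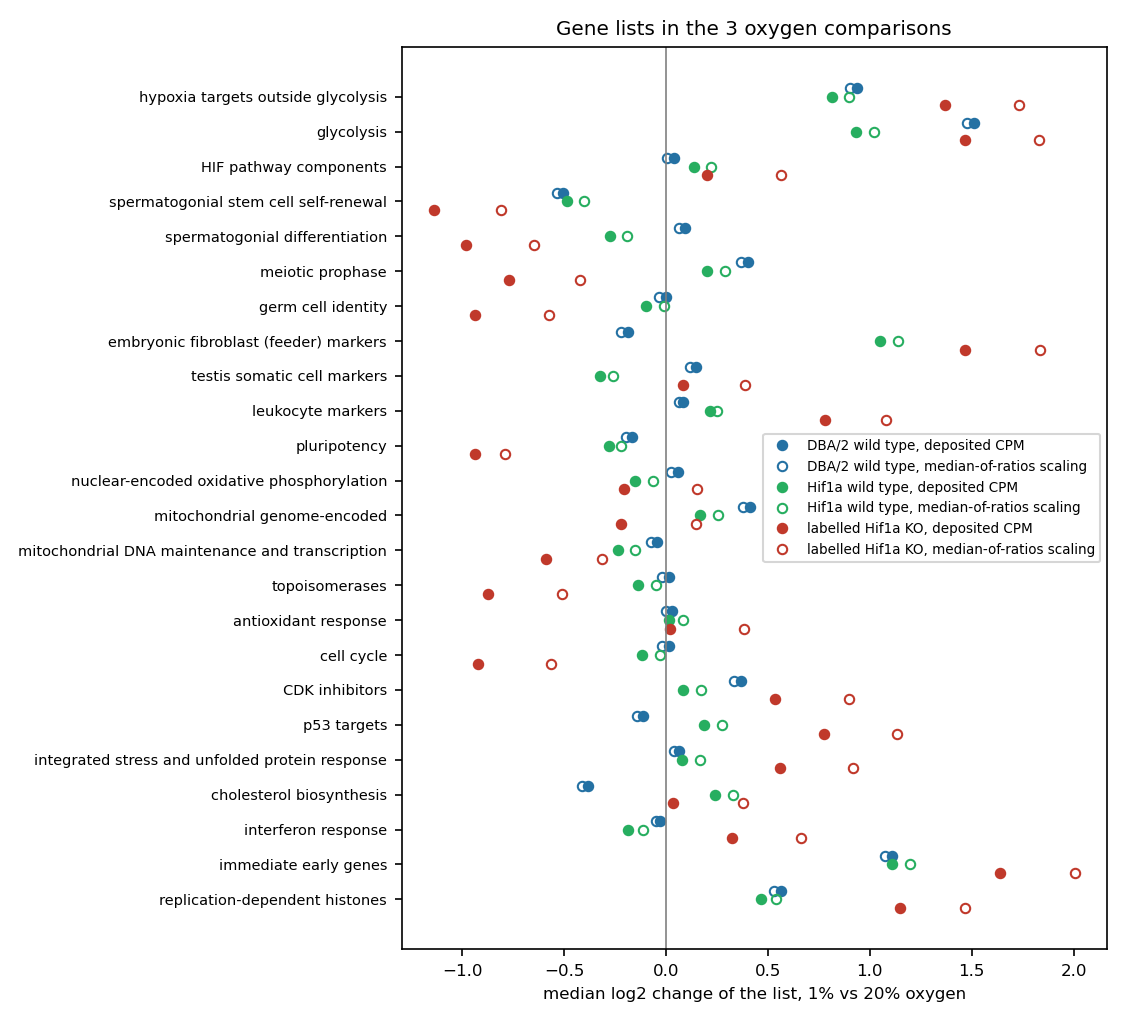
Median log2 fold change from 20% to 1% oxygen of each of the 24 gene lists in DBA/2 (blue), Hif1a wild type (green) and libraries labelled Hif1a KO (red), from deposited CPM (filled) and after median-of-ratios scaling (open). Hypoxia targets lay at 0.93, 0.81 and 1.37, and feeder markers at -0.19, 1.05 and 1.47; nuclear oxidative phosphorylation changed sign with scaling in the libraries labelled Hif1a KO (-0.21 to 0.15), as did the mitochondrial genome there (-0.22 to 0.15), and in DBA/2 cells topoisomerases (0.01 to -0.02), cell cycle genes (0.01 to -0.02) and antioxidant genes (0.030 to -0.0023).

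The test of the label against the oxygen response was the interaction, the oxygen change in libraries labelled Hif1a KO minus that in wild type. Loss of HIF1A activity would make the rise of hypoxia genes smaller. In the libraries labelled Hif1a KO the rise was larger, and so was the rise of feeder markers, though neither list call held with an estimated correlation. The interaction was called for 8603 genes, 2819 positive and 5784 negative, with a median over all genes of -0.17; after median-of-ratios scaling this median was 0.069 and the positive share went from 32.8% to 61.7%. After germ rescaling 10848 were positive and 95 negative. Median-of-ratios scaling moved log2 differences by 0.27 and germ rescaling by 0.86. For hypoxia targets outside glycolysis 21 of 35 were higher and 6 lower (21 and 6 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 2.4e-07, adjusted p = 0.13 with an estimated correlation), 0.69 with 26 higher and 4 lower after median-of-ratios scaling, and 1.30 with 33 and 0 after germ rescaling. For glycolysis 18 of 22 were higher and 2 lower (18 and 2 adjusted over the list alone). Their median was 0.45 (camera adjusted p = 3.0e-08, adjusted p = 0.14 with an estimated correlation), 0.73 after median-of-ratios scaling and 1.34 after germ rescaling. Slc16a3 stood at 1.24 ± 0.12, Egln3 at 1.163 ± 0.09, Bnip3 at 0.98 ± 0.09 and Hif1a itself at 1.01 ± 0.08, while Vegfa was not called (0.26 ± 0.13, adjusted p = 0.084). A call for Vegfa was made with median-of-ratios scaling (0.54), edgeR, DESeq2, pseudocount 4 or the replicate block, and without either of 2 libraries. Feeder markers had a median of 0.46 (camera adjusted p = 1.4e-07, adjusted p = 0.26 with an estimated correlation) and germ cell identity genes -0.92 (camera adjusted p = 1.3e-08, adjusted p = 0.13 with an estimated correlation). The cell cycle median was -0.84 (camera adjusted p = 8.4e-08, adjusted p = 0.13 with an estimated correlation), and 0.03 after germ rescaling, with Mki67 at -1.05 ± 0.09. The p53 targets had a median of 0.58 (camera adjusted p = 1.4e-07, adjusted p = 0.13 with an estimated correlation), with Ccng1 at 1.12 ± 0.09 and the adhesion gene Perp at 1.60 ± 0.17. The heme oxygenase Hmox1 stood at 1.19 ± 0.09 and Kit at -1.19 ± 0.08.

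At 1% oxygen, libraries labelled Hif1a KO were compared with wild type ones directly. Feeder markers were higher, while germ cell identity and cell cycle genes were lower relative to all reads, and the cell cycle list turned to higher after germ rescaling. Most hypoxia and glycolysis genes were higher, and p53 targets were higher. None of these list calls held with an estimated correlation. Hif1a itself was higher, at 606 ± 17.7 against 251 ± 0.0154 CPM (log2 fold change 1.27 ± 0.06, adjusted p = 1.0e-12). Of the tested genes, 4205 were higher and 7283 lower, 1141 and 753 of them at least 2-fold. The median over all genes was -0.21, and median-of-ratios scaling moved log2 differences by 0.28 and the higher share of calls from 36.6% to 54.3%. Germ rescaling moved log2 differences by 1.10, and 12309 genes were then higher and 116 lower.

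Of the feeder markers 24 of 24 were higher and 0 lower (24 and 0 adjusted over the list alone). Their median was 0.90 (camera adjusted p = 2.8e-11, adjusted p = 0.17 with an estimated correlation). The actin Acta2 stood at 487 ± 1.90 against 118 ± 22.0 CPM, and vimentin (Vim) at 1.66 ± 0.12. The muscle actin Acta1 had the largest difference (3.98 ± 0.23), followed by the ectoenzyme Bst1 (2.91 ± 0.14), the cornified-envelope gene Sprr1a (2.85 ± 0.21) and the lysosomal glycoprotein Gpnmb (2.52 ± 0.14). Hypoxia targets outside glycolysis had a median of 0.64 (camera adjusted p = 7.5e-06, adjusted p = 0.17 with an estimated correlation). Of these, 26 of 35 were higher and 7 lower (26 and 7 adjusted over the list alone). Bhlhe40 was higher by 1.54 ± 0.09, the lipase inhibitor Angptl4 by 1.30 ± 0.08, Egln3 by 0.92 ± 0.06 and Vegfa by 0.73 ± 0.09, while the demethylase Kdm3a was lower (-0.82 ± 0.05). Glycolysis had a median of 0.55 (camera adjusted p = 3.1e-06, adjusted p = 0.17 with an estimated correlation). Of these, 18 of 22 were higher and 2 lower (18 and 2 adjusted over the list alone), with lactate dehydrogenase Ldha at 1.35 ± 0.08, Pgk1 at 1.37 ± 0.09 and Slc2a3 at -1.13 ± 0.06. The p53 targets had a median of 0.98 (camera adjusted p = 2.4e-07, adjusted p = 0.17 with an estimated correlation). Of these, 15 of 18 were higher and 1 lower (15 and 1 adjusted over the list alone), with Perp at 2.37 ± 0.12 and Ccng1 at 1.71 ± 0.06, and Cdkn1a stood at 1.42 ± 0.10.

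Of the germ cell identity genes 0 of 16 were higher and 16 lower (0 and 16 adjusted over the list alone). Their median was -1.14 (camera adjusted p = 2.7e-07, adjusted p = 0.17 with an estimated correlation). Meiotic prophase genes had a median of -1.19 (camera adjusted p = 1.0e-05, adjusted p = 0.17 with an estimated correlation), and -0.09 after germ rescaling, with Stag3 at -1.31 ± 0.05 and the cohesin Smc1b at -1.33 ± 0.06. Self-renewal genes had a median of -0.75 (camera adjusted p = 0.0016, adjusted p = 0.18 with an estimated correlation), which turned to 0.28 after germ rescaling. Of these, 2 of 30 were higher and 23 lower (3 and 23 adjusted over the list alone). Differentiation genes had a median of -0.84 (camera adjusted p = 0.0091, adjusted p = 0.17 with an estimated correlation), which turned to 0.13. Zbtb16 stood at -1.06 ± 0.05, the pluripotency-linked factor Sall4 at -1.07 ± 0.05, Kit at -1.38 ± 0.06 and Stra8 at -1.51 ± 0.08. The cell cycle median of -0.95 (camera adjusted p = 1.2e-05, adjusted p = 0.17 with an estimated correlation) turned to 0.16 after germ rescaling, and Mki67 stood at -1.28 ± 0.06. The antioxidant list was higher with a median of 0.40 (camera adjusted p = 0.0073, adjusted p = 0.17 with an estimated correlation), led by Hmox1 (1.23 ± 0.06), and the interferon list with 0.53 (camera adjusted p = 0.014, adjusted p = 0.35 with an estimated correlation). These medians grew to 0.68 and 0.82 after median-of-ratios scaling, and to 1.53 and 1.57 after germ rescaling. Stress response genes had a median of 0.37 (camera adjusted p = 0.0053, adjusted p = 0.17 with an estimated correlation), CDK inhibitors 0.30 (camera adjusted p = 0.028, adjusted p = 0.17 with an estimated correlation), immediate early genes 0.77 (camera adjusted p = 7.3e-05, adjusted p = 0.24 with an estimated correlation) and histones 1.10 (camera adjusted p = 0.012, adjusted p = 0.17 with an estimated correlation). Mitochondrial DNA maintenance genes had a median of -0.49 (camera adjusted p = 0.028, adjusted p = 0.17 with an estimated correlation), which turned to 0.59 after germ rescaling, and the transferrin receptor Tfrc was lower (-1.49 ± 0.07).

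At 20% oxygen the libraries labelled Hif1a KO differed less from wild type. Feeder markers and p53 targets were higher, and germ cell identity genes were lower by small amounts relative to all reads. None of these list calls held with an estimated correlation. Hypoxia targets were not called as a list from deposited CPM. Hif1a stood at 141 ± 1.86 against 117 ± 1.11 CPM (log2 fold change 0.26 ± 0.06, adjusted p = 0.0034). Calls covered 3329 genes: 1912 were higher and 1417 lower, 29 and 0 of them at least 2-fold. This count leaned on single libraries, with 1508 genes called without wild type replicate 1 and 1574 without KO replicate 2. After germ rescaling 6574 were higher and 48 lower.

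Of the feeder markers 22 of 24 were higher and 0 lower (24 and 0 adjusted over the list alone). Their median was 0.52 (camera adjusted p = 4.9e-18, adjusted p = 0.28 with an estimated correlation), led by Ccn2 (1.10 ± 0.11), thrombospondin Thbs1 (0.89 ± 0.10) and Acta2 (0.83 ± 0.11). The largest differences were those of the stromelysin Mmp10 (1.79 ± 0.19), the elastase inhibitor Slpi (1.77 ± 0.15), Serpinb2 (1.30 ± 0.12) and cyclooxygenase Ptgs1 (1.26 ± 0.13). Of the p53 targets 11 of 18 were higher and 1 lower (12 and 1 adjusted over the list alone). Their median was 0.28 (camera adjusted p = 7.9e-08, adjusted p = 0.28 with an estimated correlation), with Ccng1 at 0.58 ± 0.06 and Cdkn1a at 195 ± 22.0 against 116 ± 6.12 CPM. Of the germ cell identity genes 0 of 16 were higher and 14 lower (0 and 15 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 1.1e-08, adjusted p = 0.28 with an estimated correlation), and meiotic prophase genes had -0.22 (camera adjusted p = 9.2e-05, adjusted p = 0.3 with an estimated correlation), which became 0.02 after germ rescaling. The piRNA-pathway helicase Tdrd9 stood at -0.39 ± 0.06. Hypoxia targets outside glycolysis had a median of -0.04, or 0.20 after germ rescaling, and a mean of 0.06 (camera adjusted p = 0.57). Of these, 8 of 35 were higher and 5 lower (9 and 7 adjusted over the list alone), against 17 higher and 0 lower after germ rescaling. Glycolysis genes had a median of 0.08 (camera adjusted p = 0.27), or 0.34 after germ rescaling. Vegfa was higher (0.47 ± 0.09), while Bnip3 was not called (-0.08 ± 0.06, adjusted p = 0.39). Self-renewal genes had a median of -0.05 (camera adjusted p = 0.14), which turned to 0.19 after germ rescaling, with 13 called higher and 0 lower, and Gfra1 was not called (-0.02 ± 0.07, adjusted p = 0.86). The antioxidant list had a median of 0.20 (camera adjusted p = 0.0032, adjusted p = 0.28 with an estimated correlation), with Nqo1 at 0.83 ± 0.13, and cholesterol synthesis genes -0.14 (camera adjusted p = 0.0022, adjusted p = 0.3 with an estimated correlation), which became 0.11 after germ rescaling, with Lss at -0.29 ± 0.05. Immediate early genes had a median of 0.31 (camera adjusted p = 1.1e-04, adjusted p = 0.32 with an estimated correlation) and histones 0.54 (camera adjusted p = 0.012, adjusted p = 0.28 with an estimated correlation). The cyclin Ccnd1 was higher (0.69 ± 0.10), and the mitochondrial coactivator Ppargc1b had the largest fall in this comparison (-0.78 ± 0.14).

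The Top1mt pair asked what loss of the mitochondrial topoisomerase does at 1% oxygen. The library names do not say whether its KO and wild type cells came from the same culture. Differences in this pair can therefore not be told from differences between separately derived cultures. The targeted gene followed its label: Top1mt (chromosome 15, 75657035 to 75678800, mm10) stood at 32.8 and 34.8 CPM in wild type and at 9.99 and 10.96 CPM in KO libraries (log2 fold change -1.60 ± 0.07, adjusted p = 1.5e-12). Self-renewal genes were lower in KO libraries, feeder markers and hypoxia genes higher. Cell cycle genes were lower too, though not relative to germ cell identity genes. None of these list calls held with an estimated correlation. Genes of the mitochondrial genome moved little. Calls covered 8668 genes: 3735 were higher and 4933 lower, 267 and 204 of them at least 2-fold, with a median over all genes of -0.04; germ rescaling moved log2 differences by 0.43 and made 89.3% of calls higher.

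Of the self-renewal genes 2 of 30 were higher and 23 lower (3 and 23 adjusted over the list alone). Their median was -0.61 (camera adjusted p = 1.4e-07, adjusted p = 0.16 with an estimated correlation), and -0.21 after germ rescaling, with 7 called higher and 15 lower. Gfra1 stood at 57.0 ± 3.91 against 288 ± 7.35 CPM (log2 fold change -2.32 ± 0.07, adjusted p = 1.5e-15), Ret at -1.41 ± 0.04, the GDNF-induced factor Etv5 at -1.50 ± 0.06 and Zbtb16 at -1.39 ± 0.05. Lhx1, induced by GDNF as well, stood at -1.86 ± 0.16 and the receptor subunit Chrna4 at -2.60 ± 0.06, the largest fall. The differentiation list had a median of 0.03 and a mean of 0.21 (camera adjusted p = 0.55), and a median of 0.47 after germ rescaling, with the uridine phosphorylase Upp1, the largest rise of the comparison, at 3.08 ± 0.12, and Kit at -0.28 ± 0.06. Cell cycle genes had a median of -0.44 (camera adjusted p = 2.1e-06, adjusted p = 0.16 with an estimated correlation), and 0.00 after germ rescaling. Of these, 2 of 26 were higher and 22 lower (2 and 22 adjusted over the list alone), with the cell cycle transcription factor E2f1 at -0.84 ± 0.05, the replication clamp Pcna at -0.89 ± 0.06 and Mki67 at -0.63 ± 0.06. Of the germ cell identity genes 0 of 16 were higher and 15 lower (0 and 15 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 1.5e-05, adjusted p = 0.34 with an estimated correlation), and the meiotic list had -0.18 (camera adjusted p = 0.023, adjusted p = 0.52 with an estimated correlation), which turned to 0.26 after germ rescaling.

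Of the feeder markers 24 of 24 were higher and 0 lower (24 and 0 adjusted over the list alone). Their median was 0.90 (camera adjusted p = 3.6e-14, adjusted p = 0.31 with an estimated correlation). Acta2 stood at 1431 ± 37.4 against 334 ± 9.37 CPM, Tagln at 1.98 ± 0.11 and the lipocalin Apod at 2.64 ± 0.13. Hypoxia targets outside glycolysis had a median of 0.55 (camera adjusted p = 1.4e-07, adjusted p = 0.16 with an estimated correlation). Of these, 23 of 35 were higher and 4 lower (23 and 4 adjusted over the list alone), with the prolyl hydroxylase P4ha2 at 1.00 ± 0.07, Bnip3 at 0.90 ± 0.06 and Vegfa at 0.80 ± 0.09. Glycolysis genes had a median of 0.39 (camera adjusted p = 2.8e-05, adjusted p = 0.35 with an estimated correlation). Of these, 16 of 22 were higher and 4 lower (16 and 4 adjusted over the list alone), with Ldha at 0.96 ± 0.08, Tpi1 at 0.83 ± 0.07 and Pdk1 lower at -0.44 ± 0.05. Hif1a stood at 0.20 ± 0.06, a call that ended without wild type replicate 2. Of the histones 6 of 6 were higher and 0 lower (6 and 0 adjusted over the list alone). Their median was 0.76 (camera adjusted p = 0.0036, adjusted p = 0.22 with an estimated correlation), among them the linker histone Hist1h1c (1.31 ± 0.10). Reads of such genes can be shared among close copies, and the list was fixed as a sign of RNA quality.

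Of the 13 protein genes of the mitochondrial genome, 7 could be tested, since mt-Atp6, mt-Atp8, mt-Co3, mt-Nd3 and mt-Nd4l had 0 reads in all 16 libraries and mt-Co2 had 1 read. With mt-Co1 at 4527 to 10046 CPM, values of 0 for genes transcribed from the same DNA are a matter of counting or alignment, not of expression. Over the 7 genes in the Top1mt pair 0 of 7 were higher and 2 lower (0 and 1 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.55), and mt-Nd5 stood at -0.34 ± 0.09; the median turned to 0.29 after germ rescaling. Nuclear oxidative phosphorylation genes had a median of 0.02 (camera adjusted p = 0.55), or 0.46 after germ rescaling, with 37 higher and 3 lower. From deposited CPM 12 of 42 were higher and 9 lower (12 and 9 adjusted over the list alone), with the respiratory subunit Ndufv1 at -0.77 ± 0.06 and Ndufa4l2 at 1.33 ± 0.13. Mitochondrial DNA maintenance genes had a median of -0.24 (camera adjusted p = 0.096), which turned to 0.19 after germ rescaling. Of these, 1 of 17 were higher and 10 lower (1 and 11 adjusted over the list alone), with the nuclease Mgme1 at -0.76 ± 0.08 and the helicase Twnk at -0.53 ± 0.07. The topoisomerase list, which leaves out Top1mt, had a median of -0.28 (camera adjusted p = 0.1), and turned to 0.17 after germ rescaling. Of these, 1 of 7 were higher and 6 lower (1 and 6 adjusted over the list alone), with Top2a at -0.61 ± 0.05, Top1 at -0.51 ± 0.06 and Top2b higher at 0.65 ± 0.06. The testis somatic, leukocyte and pluripotency lists had medians of 0.45 (camera adjusted p = 0.15), 0.02 (camera adjusted p = 0.78) and -0.20 (camera adjusted p = 0.86), the last turning to 0.23 after germ rescaling. The interferon list had 0.07 (camera adjusted p = 0.55), or 0.50 after germ rescaling, and cholesterol synthesis genes -0.11 (camera adjusted p = 0.072), which turned to 0.33.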

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

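The tests of technical explanations in this part, and germ rescaling, were chosen after the results they weigh had been seen, while median-of-ratios scaling and the estimated correlation were settings fixed in advance. What brought the results here is a tested difference between groups in their response to oxygen, either between libraries labelled Hif1a KO and wild type or between the Hif1a wild type and DBA/2 lines.

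The oxygen response differed between libraries labelled Hif1a KO and wild type for 8603 genes. Lists with a positive median difference were hypoxia targets outside glycolysis (0.41), glycolysis (0.45), feeder markers (0.46), leukocyte markers (0.37), the antioxidant response (0.21), CDK inhibitors (0.48), p53 targets (0.58), the stress and unfolded protein response (0.27), the interferon response (0.40), immediate early genes (0.44) and replication-dependent histones (0.56). Lists with a negative median were self-renewal (-0.63), differentiation (-0.84), meiotic prophase (-0.97), germ cell identity (-0.92) and the cell cycle (-0.84). None of these calls held with an estimated correlation, where adjusted p was 0.13 for hypoxia targets, 0.16 for leukocyte markers, 0.26 for antioxidant genes and 0.37 for interferon genes. After germ rescaling, which centres the germ cell identity list by construction, self-renewal (0.23) and cell cycle genes (0.032) turned positive, and differentiation (-0.0041) and meiotic prophase (-0.13) came near 0. The positive medians grew, to 1.30 for hypoxia targets, 1.34 for glycolysis and 1.08 for antioxidant genes (0.69, 0.73 and 0.48 after median-of-ratios scaling). Among single genes the difference was 1.24 for Slc16a3, 1.163 for Egln3, 0.98 for Bnip3, 1.01 for Hif1a, 1.12 for Ccng1, 1.60 for Perp, 1.19 for Hmox1, -1.19 for Kit and -1.05 for Mki67.

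The oxygen response differed between the Hif1a wild type and DBA/2 lines for 6830 genes. The lists called were glycolysis (-0.55), differentiation (-0.49), feeder markers (1.21), p53 targets (0.30) and cholesterol synthesis (0.56), with adjusted p = 0.52, 0.47, 0.52, 0.52 and 0.073 with an estimated correlation. Among single genes the difference was 4.70 for Lum, 4.67 for Serpina3n, 1.54 for Vegfa, 1.30 for Pdk1, 1.10 for Hif1a, 0.91 for Cyp51, 0.83 for Hmgcs1, -1.62 for Slc2a3, -1.87 for Pfkp and -3.21 for Krt19.

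Hypoxia targets and glycolysis genes were higher in libraries labelled Hif1a KO than in wild type at 1% oxygen, with a median of 0.58 over 57 genes. More RNA from feeder cells could account for this, since the same genes differed alike in the Top1mt pair, where no Hif1a allele was targeted (r = 0.83, same sign for 53 of 57). The genes are not independent replicates, all genes together gave r = 0.67, and 2000 random lists of matched level gave a median of 0.75 (0.55 to 0.86 without the outer 2.5% on each side), so the likeness is not special to hypoxia genes. Median-of-ratios scaling, which takes the typical gene as unchanged, left a median of 0.86 with 48 genes higher and 8 lower. It moved log2 differences up by 0.28 in this comparison, so a positive median could only grow. Relative to the typical gene, scaling to a fixed total is thus not the whole cause, but a change in the mixture of cells is not excluded. A biological explanation, a stronger response in cells without HIF1A, was not tested apart from the label.

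The Hif1a transcript was higher in libraries labelled Hif1a KO than in wild type at 1% oxygen. Feeder RNA does not explain it if its profile and share are those of the Top1mt pair. There Hif1a differed by only 0.20 ± 0.06, with feeder medians of 0.90 and 0.90 in the pairs. The mixtures were not alike, since these medians were 2.04 in the Hif1a pair and 1.35 in the Top1mt pair after germ rescaling. In the Hif1a line, wild type and KO at 20% and then at 1% oxygen, Hif1a stood at 117, 141, 251 and 606 CPM. The feeder sums of these groups rose in the same order, from 13775 to 72626 CPM. Feeder RNA of another profile or share therefore stays open. Relative to the typical gene, scaling does not explain it, with a difference of 1.55 ± 0.06 after median-of-ratios scaling. That scaling moved log2 differences up by 0.28, so a positive difference could only grow. An exchange of the KO and wild type labels at 1% oxygen may be neither shown nor excluded: the hypoxia targets had a median interaction of 0.41, but KO and wild type differed alike at 20% and 1% oxygen (r = 0.77 over all genes, which are not independent replicates). Loss of an exon that leaves a counted transcript could be why the count was not lower, and gene-level values cannot test it. It would not by itself account for a higher count, for which no biological explanation was tested.

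Cholesterol synthesis genes fell in DBA/2 cells at 1% oxygen (0 of 24 rose and 18 fell) and tended to rise in Hif1a wild type cells (12 rose and 1 fell). Relative to the typical gene, scaling was not the whole cause, as the median difference between lines was 0.68 after median-of-ratios scaling. That scaling moved log2 differences between the lines up by 0.12, so a positive median could only grow. More feeder RNA in the Hif1a libraries stays open. In the Top1mt pair, where feeder markers were higher as well, 12 cholesterol genes were lower and 1 higher (10 and 3 after median-of-ratios scaling), but 2 were lower and 15 higher after germ rescaling. A different library set or time in low oxygen for the Hif1a libraries may be the cause and cannot be told from the line itself. In the libraries labelled Hif1a KO, which share both, the median was 0.032 from deposited CPM, 0.38 after median-of-ratios scaling (16 rose and 2 fell) and 0.94 after germ rescaling (24 rose and 0 fell).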

How the results depend on the processing

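Germ rescaling and the fit without feeder-associated genes were chosen after the results were seen, and all other settings were fixed in advance. All 8 counts of called genes stayed within 1.5 times under every setting fixed in advance that left out no replicate, and no named gene changed direction with a call under any of them. KO against wild type in the Hif1a line at 20% oxygen, with 3329 genes, was the exception among fits that left out 1 library (1508 to 2957). In those fits the lone library of a group was assumed to vary like the other groups. That count was 6622 after germ rescaling, 6574 of them higher, and 1259 without feeder-associated genes, which leaves out higher genes by construction. Germ rescaling kept the other counts within 1.5 times. Like counts did not mean like calls. Of 8047 interaction calls after median-of-ratios scaling, 5900 were also called in the same direction in the main fit. After germ rescaling this held for 2914 of 10943 interaction calls and for 4899 of 11606 in labelled Hif1a KO cells. Germ rescaling made 90.1% of calls higher or positive in labelled Hif1a KO cells, 99.1% in the interaction and in KO against wild type at 1%, and 89.3% in the Top1mt pair, against 46.0% in Hif1a wild type cells and 40.9% in the line difference. The fit without feeder-associated genes went the other way, with 18.3% of calls higher in labelled Hif1a KO cells and 23.9% in Hif1a wild type cells. The rule for these genes favours low values in Hif1a wild type libraries at 20% oxygen. Fewer rises in Hif1a wild type cells were thus partly fixed by that choice. Ranges over left-out libraries for the other counts were 6932 to 7235 in DBA/2, 6175 to 7387 in Hif1a wild type and 10972 to 11367 in labelled Hif1a KO cells. They were 7537 to 8753 for the interaction, 10539 to 11196 for KO against wild type at 1%, 7350 to 7610 for Top1mt and 5650 to 6906 for the line difference. edgeR called 8843 genes in DBA/2 cells and DESeq2 7642, and for the interaction 7688 and 6555.

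Replicate numbers in the library names are shared between groups but are not said to mark a shared culture, so no pairs were assumed. With a replicate block within each line, counts in the order DBA/2, Hif1a wild type, labelled Hif1a KO, interaction, KO against wild type at 1% and at 20%, Top1mt and line difference were 8760, 8151, 11924, 8833, 11541, 3804, 8826 and 7151. Differences between replicates 1 and 2 correlated across 11797 genes with r from -0.11 to 0.44 between groups, where genes are not independent replicates. Under the block, the median of genes that fell in DBA/2 cells was called in the Top1mt pair (0.0422). HIF pathway components in labelled Hif1a KO cells and antioxidant genes in the interaction were no longer called, and CDK inhibitors in Hif1a wild type cells and Vegfa in the interaction were called.

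Of the list tests, 83 camera calls were lost with an estimated correlation. fry tests against 0 and not against other genes, and added 54 calls in the direction of camera, lost 2, and turned 3 lists to lower: testis somatic markers in labelled Hif1a KO cells (adjusted p = 5.9e-04), and nuclear oxidative phosphorylation in the interaction (0.0087) and in KO against wild type at 1% (0.0013).

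The lists of genes that rose or fell in DBA/2 cells depended most on the fold limit. Without it, medians for risen genes turned negative in labelled Hif1a KO cells (-0.13), the interaction (-0.14), KO against wild type at 1% (-0.17) and at 20% (-0.011) and the Top1mt pair (-0.031). Those for fallen genes turned negative in the interaction (-0.22), KO against wild type at 1% (-0.29) and at 20% (-0.056) and the Top1mt pair (-0.074), and the one in labelled Hif1a KO cells (-0.52) became a call. Over left-out libraries, medians for fallen genes ran from -0.046 to 0.133 in the interaction and from -0.095 to 0.285 in KO against wild type at 1%. They ran from -0.659 to -0.320 in labelled Hif1a KO cells, from -0.502 to -0.326 in Hif1a wild type cells, where 1 fit ended the call, and from 0.0028 to 0.157 in the Top1mt pair, where 3 fits made a call. The interaction median was 0.24 and no longer called after median-of-ratios scaling. The Top1mt median became a call with pseudocount 0.25 (0.12), a filter at CPM 5 (0.085) or only the groups compared (0.0422). The cause was not tested.

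Depth limits genes near the floor of 0.117 to 0.251 CPM. With 2 libraries a group, changes of 1.5-fold were recovered less often (76%) than those of 2-fold (96%) in simulated interactions.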

Other observations

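The gene lists in this part were fixed before the data were examined, except the genes that rose or fell at least 2-fold in DBA/2 cells, which were drawn from the data by a rule fixed in advance. Germ rescaling was chosen after results were seen. In the stress and unfolded protein response list the mitochondrial hydroxymethyltransferase Shmt2 (-0.84 ± 0.06) and the dehydrogenase Phgdh (-0.67 ± 0.06) fell in DBA/2 cells at 1% oxygen. Over the whole list 6 of 20 rose and 4 fell (6 and 3 adjusted over the list alone), with a median of 0.06 (camera adjusted p = 0.71), as the stress factor Atf3 rose by 1.68 ± 0.09. In Hif1a wild type cells the asparagine synthetase Asns fell (-0.91 ± 0.06) while the stress regulator Nupr1 rose by 1.18 ± 0.11. The cystine transporter Slc7a11 (-1.96 ± 0.18) and sulfiredoxin Srxn1 (-1.04 ± 0.09) fell in DBA/2 cells, while the glutathione synthesis subunit Gclm rose by 0.78 ± 0.06. Antioxidant genes had a median of 0.03 and a mean of -0.07 there (camera adjusted p = 0.98).

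Of 7 pluripotency genes tested, 3 rose and 2 fell in DBA/2, 1 rose and 3 fell in Hif1a wild type, and 1 rose and 6 fell in labelled Hif1a KO cells. Pou5f1, a core pluripotency factor that undifferentiated spermatogonia also express, fell in DBA/2 (-0.86 ± 0.12), Hif1a wild type (-1.12 ± 0.12) and labelled Hif1a KO cells (-1.50 ± 0.12), while Klf4 rose by 0.57 ± 0.07, 1.12 ± 0.07 and 1.57 ± 0.07. The list had medians of -0.17 (camera adjusted p = 0.76), -0.28 (camera adjusted p = 0.76) and -0.94 (camera adjusted p = 0.3), the last -0.42 with 2 rising and 4 falling after germ rescaling. The interferon-induced Oasl2 rose by 2.15 ± 0.14, 1.11 ± 0.14 and 1.51 ± 0.14, while the RNA sensor Ifih1 fell (-1.49 ± 0.12, -0.94 ± 0.12 and -1.14 ± 0.12). The interferon list had medians of -0.03 (camera adjusted p = 0.34), -0.19 (camera adjusted p = 0.52) and 0.32 (camera adjusted p = 0.15), the last 1.19 after germ rescaling.

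Genes that rose at least 2-fold in DBA/2 cells at 1% oxygen were higher in KO libraries of the Top1mt pair, with a median of 0.31, where 177 of 356 were higher and 67 lower (camera adjusted p = 1.0e-07, adjusted p = 0.12 with an estimated correlation). Without the fold limit on the list, this median in the Top1mt pair turned negative but stayed above the median of -0.044 over all genes. The genes that fell at least 2-fold had a median of 0.04 there (camera adjusted p = 0.071). The Top1mt transcript fell at 1% oxygen in the libraries labelled Hif1a KO as well, from 47.8 ± 0.406 to 24.5 ± 0.0403 CPM (-0.93 ± 0.07), beside medians of -0.29 over all genes and -0.94 over germ cell identity genes.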
